A study of Mus musculus with 6 samples.

How the data were processed

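RNA of skin from 3 Tcfap2c mutant and 3 control mouse embryos at embryonic day 16.5 was hybridised to Affymetrix mouse arrays, 1 array per sample. Total RNA was extracted with a Qiagen kit and labelled with biotin by Affymetrix protocols, per the labels' protocols. The deposited values are MAS5 signals, an intensity per probe set on a linear scale, and MAS5 is named in the submitters' processing notes without a version. In each of the 6 columns the mean after trimming 2% at each end was 500, so the authors' deposited intensity had been scaled array by array. Detection calls were not used here. Groups were taken from the titles.

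The signals were analysed on the log2(signal + 24.48) scale, where 24.48 is the 20th percentile of all values, so fold changes of dim probe sets are understated. No further normalization was applied. The 64 Affymetrix control probe sets were left out. Probe sets were kept when their mean log2 over all 6 arrays lay above the median (a signal of about 114.5), which left 22518 of 45101 probe sets and 11589 genes. As a measure of background, 9 Y-linked probe sets in the 3 arrays with high Xist had a median signal of 6.35. Gene names came from the platform annotation in GEO, updated through gene identifiers against the mouse RefSeq table (GRCm38.p6), which was used for names and neighbouring genes only. There were 34958 probe sets with 1 gene symbol, 932 with several and 9211 with none, and genes were named only from those with 1. Each gene was represented by its probe set with the highest mean.

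Differences (mutant minus control) were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over 23 lists. The design, the lists, the rule for named genes and most other settings were fixed before the data were examined. The rule named the AP-2 family, up to 12 genes in each direction past the threshold, up to 4 members of each list with the smallest p, and 8 fixed keratinocyte genes (Krt1, Krt10, Krt5, Krt14, Lor, Flg, Ivl and Trp63). A direction with fewer than 5 genes was filled to 5 by the smallest unadjusted p, and such genes are reported as not past the threshold. Klk5, Lce3f and genes named for mutant sample 1 fall outside the rule and were chosen after their values were seen.

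The test was tried on simulated data of 22518 independent probe sets with 3 against 3 samples. It recovered 36.7% of probe sets changed by 1 on the log2 scale, 74.9% of those changed by 2 and 79.3% of those changed by 3, with 3.97% false among the calls. A list of 40 genes shifted by -0.5 was found in 20 of 20 simulations and an unchanged list in 1 of 20, by camera with the preset correlation. Each simulation changed 200 probe sets besides that list. These rates hold only for uncorrelated genes and for that number of changed probe sets. Where fewer change, the adjustment is stricter and recovery would be lower. The cornified envelope list had an estimated correlation of 0.224 between its genes. Exact permutation of 3 against 3 samples cannot give a two-sided p below 0.1.

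The other settings were other pseudocounts, other filters, quantile normalization, median centring, other variance models, array weights, and the replicate number as a block. Further settings were each sample left out in turn, an adjusted p under 0.1, and the mean over a gene's probe sets. In another, probe sets with names ending in _s_at, _x_at or _a_at were left out. The _a_at ending can mark transcripts of 1 gene, so this also removed probe sets of single genes. A fit with the Xist signal as a covariate, the cornified envelope list without the Lce1 and Sprr2 families, an estimated correlation in camera under the other settings, and 1 probe set per gene before the adjustment were added after seeing the data. Figures were drawn with matplotlib 3.10.9.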

Results

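The data were 6 one-colour Affymetrix mouse arrays of skin RNA taken at embryonic day 16.5. There were 3 samples from Tcfap2c mutant embryos and 3 from control embryos. Tcfap2c, now named Tfap2c, encodes AP-2 gamma, a transcription factor of the AP-2 family that is made in the surface ectoderm and its epidermis. Titles, source names and the series design place 3 samples in the control group, although the description field of those same samples also mentions the mutation. The series title speaks of epidermis and the sample labels of skin. The labels do not say whether samples came from separate litters, so p-values measure the spread between these 6 samples. Every array had a trimmed mean signal of 500, and the median signal per array lay between 110.4 and 131.5. The number of arrays limits the precision.

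Mutant sample 1 stood apart from the other 5. Its score on the first principal component, which held 44.6% of the variance, was -65.1, against 0.35 to 28.3 in the others. Its mean correlation with the other arrays was 0.94, against at least 0.961 for each of the others. Transcripts with far higher signal in that sample than in the others included Prl8a2, a decidual prolactin-family hormone, at 14200 against at most 61.2, and Prap1, a secreted protein of uterine and gut epithelium, at 36050 against at most 359.1. Actg2, the smooth muscle gamma actin, was at 13440 against at most 450.5. These 3 genes were chosen after their values were seen. Xist, transcribed from the inactive X chromosome, was high in mutant sample 1 (10840) and in control samples 1 and 2 (6479 and 6599), and Eif2s3y, a Y-linked gene, was high in the remaining samples.

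**Figure D1:**
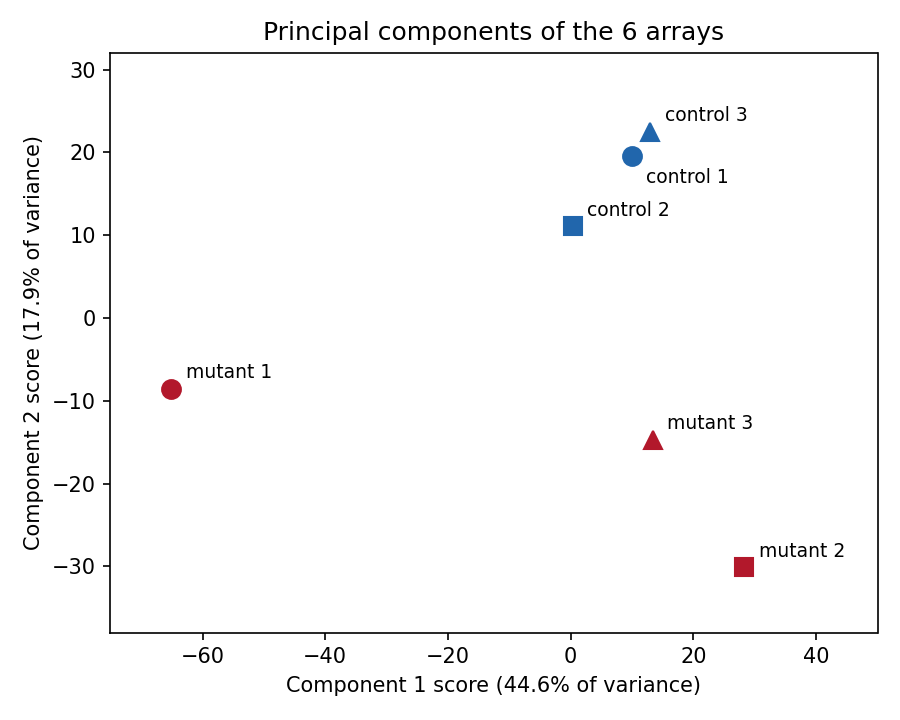
Scores of the 6 arrays on the first 2 principal components of the log2 signals of 22518 probe sets, with the share of variance in percent on each axis (red, Tcfap2c mutant; blue, control; the symbol gives the replicate number). Mutant sample 1 lies at -65.1 on the first component and the other 5 samples between 0.35 and 28.3.

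The comparison asked which transcripts of embryonic skin differ when Tcfap2c is mutated. Tfap2c itself was measured by 3 probe sets. The probe set with the highest signal gave 1412 ± 175 in mutant and 1290 ± 85 in control samples (SD, n = 3 each), a log2 difference of 0.12 (SE 0.14). The other probe sets gave 0.14 and 0.01, and none passed the test. The labels do not say which part of the gene is altered, so these values do not check the labels. Tfap2a differed by -0.13 and Tfap2b by -0.16 on the log2 scale. Tfap2e differed by 0.04, and none of these passed the test.

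Sftpd, which encodes surfactant protein D, a secreted lectin of innate defence, rose in mutant skin. Its signal was 1229 ± 396 in mutant and 84.4 ± 7.0 in control samples (SD, n = 3 each). The log2 difference was 3.48 (SE 0.23), an 11.2-fold increase with an adjusted p of 0.00245 in limma, and each mutant sample lay above every control sample. Sftpd was the 1 probe set of 22518 that passed an adjusted p of 0.05, and 0 passed in the lower direction. At an unadjusted p under 0.05 there were 771 probe sets, 327 higher and 444 lower, or 3.42% of those tested. With 1 sample left out this count was between 435 (without control sample 3) and 1607 (7.14%, without mutant sample 1), and it was 1298 without mutant sample 2. Mutant and control samples did not overlap for 1875 probe sets (8.33%, where chance gives 10%). The number of probe sets past an adjusted p of 0.05 was 39 without mutant sample 1, with 25 higher and 14 lower. With array weights 106 passed that threshold, with 47 higher and 59 lower. The weights of mutant samples 1, 2 and 3 were 0.257, 0.56 and 3.13, so the mutant mean then rested mostly on mutant sample 3.

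The next genes by p did not pass the threshold with all 6 samples. Among those with higher signal in the mutant samples were Gng4, a G protein gamma subunit, with a log2 difference of 1.90 (limma adjusted p = 0.122), and Emb, the membrane glycoprotein embigin, with 1.33 (adjusted p = 0.20). Atp1b1, a subunit of the sodium pump, differed by 0.93, and Gpx3, a secreted glutathione peroxidase, by 2.56. The signal of Gpx3 was 21017 ± 5858 in mutant and 4009 ± 2452 in control samples (SD, n = 3 each). Among those with lower signal were Slurp1, a secreted keratinocyte protein, with -1.52 (adjusted p = 0.122), and Shh, the hedgehog ligand of hair placodes, with -1.02 (adjusted p = 0.205). The signal of Shh was 627 ± 36 in mutant and 1300 ± 125 in control samples. Sprr2d differed by -1.19, Serpinb3a by -0.92 and Krt12, a keratin best known from cornea, by -2.04. Without mutant sample 1, Gng4, Emb, Gpx3, Slurp1, Shh, Sprr2d, Serpinb3a and Krt12 passed the threshold, with limma adjusted p between 0.0142 and 0.0489. The probe set used for Atp1b1 did not pass (adjusted p = 0.0717), and another of its probe sets did (adjusted p = 0.0269).

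**Figure D2:**
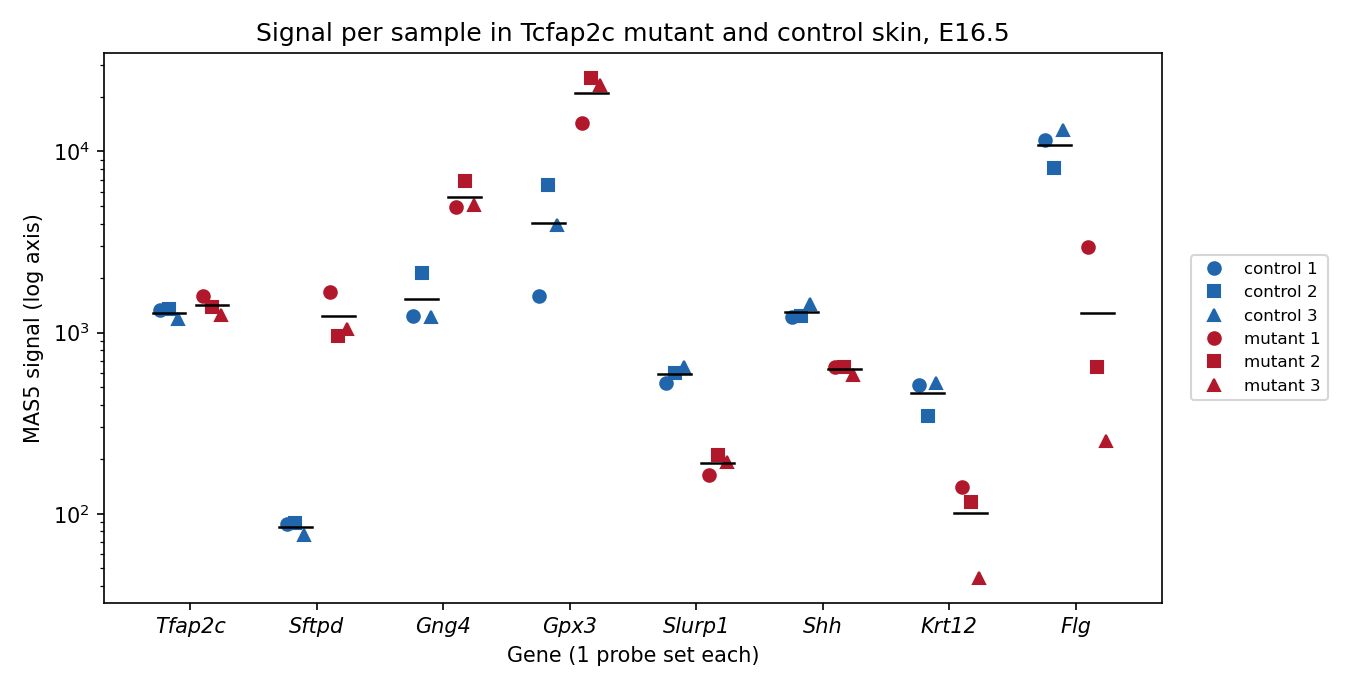
MAS5 signal (log axis) of 8 genes in each of 3 control (blue) and 3 mutant (red) samples; symbols give the replicate number and black lines the group mean. Sftpd was between 957 and 1683 in mutant samples and between 76.3 and 88.8 in control samples, and the other 7 genes did not pass the threshold with all 6 samples.

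The cornified envelope and granular layer list, genes of the last steps of epidermal differentiation, was lower in the mutant samples as a set in 1 of the tests used, camera with a preset correlation. Of 44 measured members, 34 had a negative and 10 a positive difference, with a median of -0.38 on the log2 scale. The median was -0.23 without mutant sample 3, -0.24 without control sample 2 and -0.61 without mutant sample 2. It was -0.16 over the 29 genes outside the Lce1 and Sprr2 families, a setting added after seeing the data. With all 44 members, camera with the preset correlation gave an adjusted p of 8.4e-08 over 23 lists, and with an estimated correlation the adjusted p = 0.65. The list did not pass fry, either for a shift in one direction (adjusted p = 0.829) or for change in either direction (adjusted p = 0.0951). No member passed over all genes. Adjusted over the list alone, 6 members were lower and 2 higher, and without mutant sample 1 these were 15 and 7, with 3 past the threshold over all genes. Flg, the precursor of filaggrin, which bundles keratin filaments, had the largest difference, -3.70 (SE 0.69, limma adjusted p = 0.43). Its signal was 2967, 647 and 252 in mutant samples 1, 2 and 3 and 10910 ± 2586 in control samples (SD, n = 3). Without mutant sample 1, the difference of Flg was -4.64 and its limma adjusted p was 0.000512. Rptn, a filaggrin-related protein, differed by -1.73, Cdsn, the adhesion protein corneodesmosin, by -1.26, and the protease Klk5 by -1.04. Lor and Ivl, which encode the envelope proteins loricrin and involucrin, differed by -0.08 and -0.27, and their signals overlapped between groups.

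Members of the late cornified envelope families went opposite ways. All 11 measured Lce1 genes had a negative difference (median -1.16), and all 3 Lce3 genes a positive one (median 2.04), with the same signs after quantile normalization and median centring. Lce3f had a signal of 11195 ± 2253 in mutant and 2421 ± 2081 in control samples (SD, n = 3 each). The distance between the mean log2 signals of the families changed by 2.75 between groups, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 samples allow. This test was chosen after the values were seen. Probe sets of such near-identical genes can share signal. The mean log2 signal of the Lce1 genes was 10.2 in mutant sample 3 and between 12.1 and 12.9 in the other samples.

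Among genes of the other epidermal layers, the medians were -0.11 for 27 suprabasal and -0.07 for 18 basal keratinocyte genes, and neither list passed camera with all 6 samples. Without mutant sample 2 both passed camera with the preset correlation, with medians of -0.26 (adjusted p = 4.57e-05) and -0.28 (adjusted p = 0.00345), but no list did with an estimated correlation (lowest adjusted p 0.1). The medians were 0.14 and -0.0061 without mutant sample 1, where neither list passed. Krt1 differed by 0.09 and Krt10 by 0.14, Krt5 by -0.23 and Krt14 by -0.22. Trp63 lay at -0.05. The signals of these genes overlapped between groups. The barrier lipid list (25 genes) had a median of 0.00 and the junction list (11 genes) one of 0.10, and neither passed with all 6 samples.

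Among 10 simple epithelial and periderm keratins, Krt8, Krt18 and Krt19 were higher and Krt23 lower when adjusted over the list alone, and none passed over all genes. The differences were 1.19, 1.60, 1.04 and -0.46. The list passed fry's test for change in either direction (adjusted p = 0.0414), not its test for one direction (adjusted p = 0.839) and not camera (adjusted p = 0.331). Its median was 0.18 with all 6 samples, -0.029 without control sample 3 and -0.089 without _s_at, _x_at and _a_at probe sets. The list passed camera without mutant sample 1 at the preset correlation (median 0.39, adjusted p = 0.0436) and not with an estimated one (adjusted p = 0.722). Krt18 had a signal of 3253 in mutant sample 1, the sample that stood apart, and of 694 and 875 in mutant samples 2 and 3, against 404 ± 71 in control samples (SD, n = 3). Without mutant sample 1 the differences of Krt8 and Krt18 were 0.87 and 0.92.

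Of 21 hair follicle and placode genes, Shh, Ptch1 and Lhx2 were lower and Cux1 higher when adjusted over the list alone, and none passed over all genes. Ptch1, the hedgehog receptor and a target of the pathway, differed by -0.50, Lhx2, a transcription factor of follicle progenitors, by -0.64, and Cux1 by 0.71. Of the tested probe sets, 4 of 7 for Cux1 and 2 of 3 for Ptch1 shared the sign of the one used, and the others had the opposite sign. The list passed fry's test for change in either direction (adjusted p = 0.00184), not its test for one direction (adjusted p = 0.829) and not camera (adjusted p = 0.103). Its median was -0.11 with all 6 samples and 0.0048 without mutant sample 1. Without mutant sample 2 the list passed camera with the preset correlation (median -0.32, adjusted p = 0.00705) and not with an estimated one (lowest adjusted p of any list 0.1).

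The hypoxia response list was higher as a set in camera with the preset correlation, with 10 of 11 members positive (9 after quantile normalization or median centring) and a median of 0.22 (0.10 without control sample 3 and 0.32 without control sample 2). Its adjusted p was 3.7e-05, and with an estimated correlation the adjusted p = 0.65. It did not pass fry for one direction (adjusted p = 0.829) or either direction (adjusted p = 0.46). No member passed over all genes or adjusted over the list alone. Bnip3 and Slc2a1, a mitophagy receptor and a glucose transporter, differed by 0.50 and 0.45, and Ndrg1 and Egln3 by 0.44 and 0.58.

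**Figure D3:**
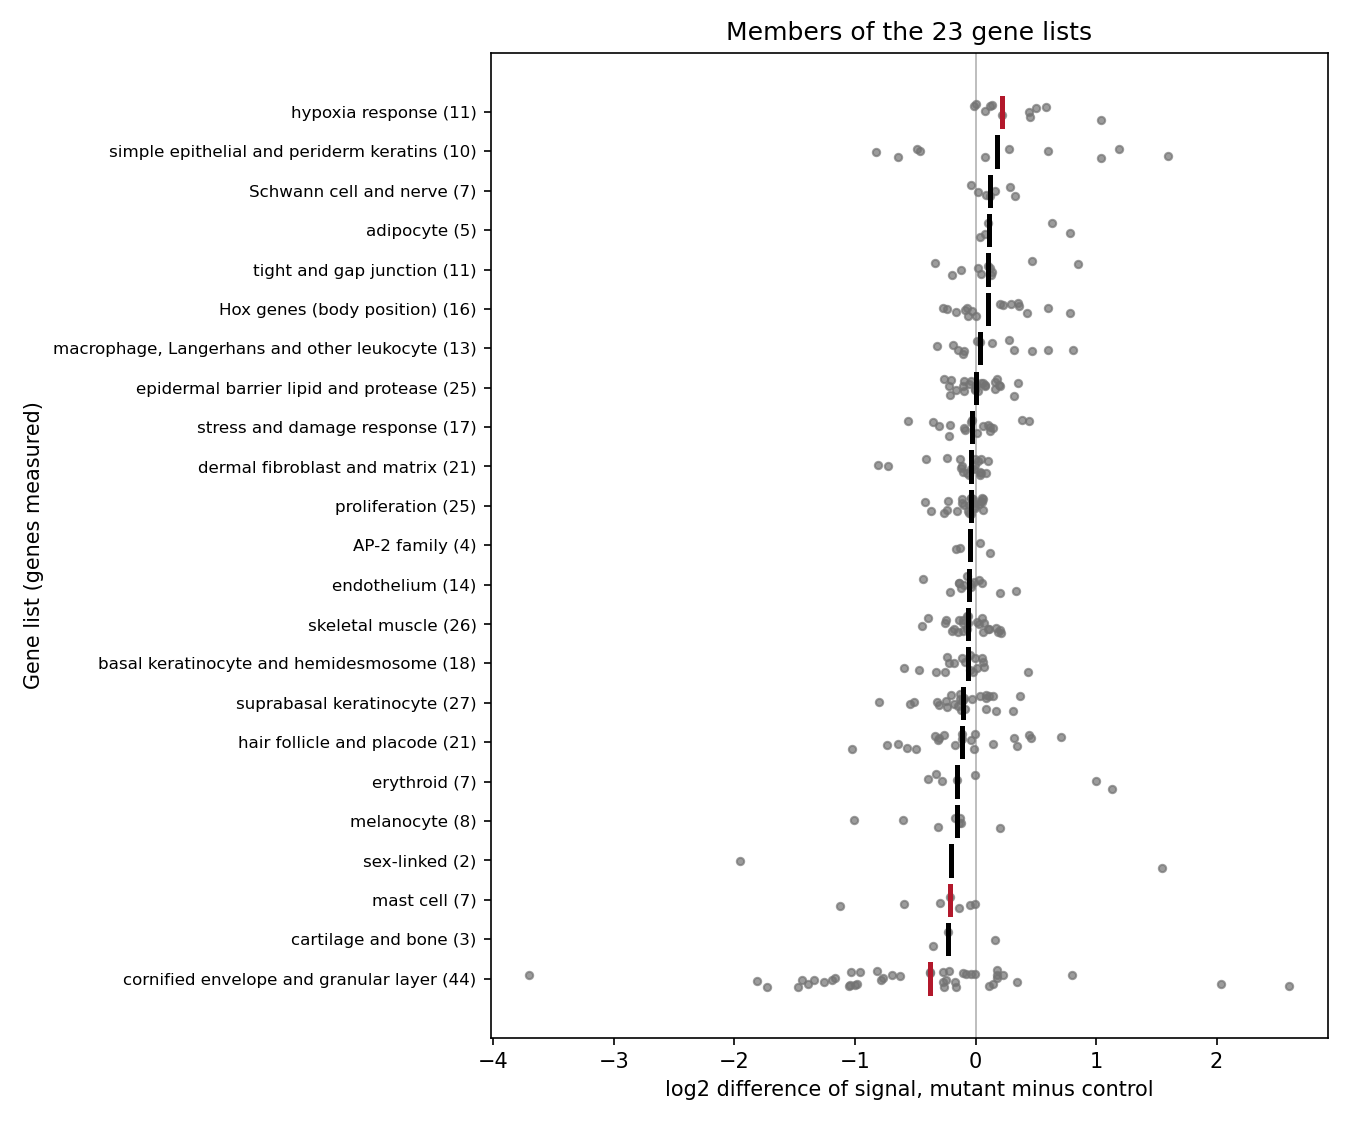
Log2 difference (mutant minus control) of each measured member (grey points) of the 23 gene lists, with the list median as a vertical line, red where camera with the preset correlation passed an adjusted p of 0.05. The cornified envelope list has the lowest median, -0.38, and the hypoxia list the highest, 0.22.

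Markers of other cell types of skin had medians between -0.23 and 0.12. The 7 mast cell genes were all negative (median -0.21), with a camera adjusted p of 0.0385 with the preset correlation, and with an estimated correlation the adjusted p = 0.65. Neither fry test passed (adjusted p = 0.829 and 0.851). The call was lost in 9 of 19 other settings, among them without mutant sample 1 (adjusted p = 0.0964), mutant sample 2 (0.164) or control sample 2 (0.196). It was also lost with array weights (0.416) and without _s_at, _x_at and _a_at probe sets (median -0.09, adjusted p = 0.618). That last setting removed the probe sets used for Cma1, Tpsb2 and Mcpt4, all named _a_at. The median was -0.37 without mutant sample 3. With the cornified envelope and hypoxia lists, 3 of 23 lists passed camera with the preset correlation. There were 5 without mutant sample 1 and 9 without mutant sample 2, and with an estimated correlation none passed in either case (lowest adjusted p 0.722 and 0.1). The median was -0.04 for 21 fibroblast and matrix genes, -0.06 for 26 skeletal muscle genes and -0.06 for 14 endothelial genes. It was 0.04 for 13 leukocyte genes, -0.15 for 8 melanocyte genes and 0.12 for 7 Schwann cell and nerve genes. For 5 adipocyte genes it was 0.11, for 3 cartilage and bone genes -0.23 and for 7 erythroid genes -0.15. In the erythroid list 5 members were negative and 2 positive. The embryonic globin Hbb-y differed by 1.14, and Hba-x had a signal of 511 ± 372 in mutant and 212 ± 67 in control samples (SD, n = 3 each). The signals of both genes overlapped between groups. The medians were -0.04 for 25 proliferation genes, -0.03 for 17 stress genes and 0.10 for 16 Hox genes. For 4 AP-2 family genes the median was -0.05 and for 2 sex-linked genes -0.20. None of these lists other than the mast cell list passed with all 6 samples. With the preset correlation the melanocyte list passed without mutant sample 1, mutant sample 2 or control sample 3, and with array weights (medians -0.18, -0.27, -0.26 and -0.32). With an estimated correlation no list passed in any of these settings (lowest adjusted p 0.722, 0.1, 0.577 and 0.733).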

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

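The Xist covariate, the list without Lce1 and Sprr2, 1 probe set per gene, and the estimated correlation under other settings were chosen after seeing the data. Sftpd passed in every setting run, with log2 differences of 2.99 to 3.82. The count of changed probe sets was 106 with array weights (47 higher, 59 lower), of which 35 were among the 39 called without mutant sample 1. Leaving out 1 sample gave 1 to 39 changed probe sets, 1 to 25 higher and 0 to 14 lower, with 39 without mutant sample 1 and 3 without control sample 2. Lists past the threshold numbered 3 with all samples and 2 to 9 with 1 left out, with 9 without mutant sample 2. With the replicate number as a block, 8 probe sets passed, all 8 higher. Deviations of same-numbered samples correlated at -0.052, -0.073 and 0.11, which gave no sign of pairing by number. They cannot exclude it, since each group mean rests on 3 samples and mutant sample 1 stood apart. The cornified envelope median stayed negative in every setting run (-0.61 to -0.16 on the log2 scale), and past the threshold in each at the preset correlation. With an estimated correlation the call was lost with all samples (adjusted p = 0.65), without mutant sample 1 (adjusted p = 0.722), and without the Lce1 and Sprr2 families (adjusted p = 0.846, against 0.0385 at the preset correlation). The mast cell call was lost in 9 of 19 settings. Lists that passed only under other settings included melanocyte with array weights (-0.32, adjusted p = 0.000825) and without mutant sample 1 (adjusted p = 0.0436), mutant sample 2 (0.011) or control sample 3 (0.0223), Hox without control sample 1 (0.14, 0.0266), proliferation without control sample 3 (-0.091, 0.00503), and adipocyte (0.33, 0.00705) and leukocyte (0.21, 0.00345) without mutant sample 2. With an estimated correlation no list passed in any setting run. That version was not tried on simulated data, and the fit of all 6 samples leaves 4 residual degrees of freedom. Its failure to pass therefore does not show that a list is unchanged. Quantile normalization and median centring moved the median of all probe sets from -0.025 to -0.017 and -0.036. Robust variance does not enter camera.

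Of 436 list values under alternatives, 42 in 14 lists had the other sign, 1 of them past the threshold, and of 1161 gene values 15 in 10 genes did, none past it. The causes were not tested. With array weights the medians were -0.031 for barrier lipid, 0.031 for stress, 0.027 for endothelium, -0.024 for adipocyte and 0.044 for cartilage and bone genes, and the differences were -0.0051 for Tfap2c, -0.20 for Tfap2e, 0.043 for Trp63 and 0.044 for Col9a1. The barrier lipid median was -4.9e-06 without a filter, -0.0044 with quantile normalization, -0.0092 with median centring and -0.039 with the Xist covariate. The sex-linked median was 0.89 with the larger pseudocount, 1.33 without a filter and 1.18 without _s_at, _x_at and _a_at probe sets. Without those probe sets, the simple keratin median was -0.089 and the leukocyte median -0.044. Without a filter the AP-2 median was 0.037. With the stricter filter the stress median was 0.016 and the Hox median -0.029, and with the mean over probe sets the Hox median was -0.011.

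Leaving out 1 sample gave these lowest and highest medians: AP-2 -0.25 and 0.053, Hox -0.12 and 0.23, Schwann cell -0.0052 and 0.25, adipocyte -0.15 and 0.33, cartilage and bone -0.34 and 0.16, endothelium -0.12 and 0.052, barrier lipid -0.048 (adjusted p = 0.0167, without mutant sample 2) and 0.14 (adjusted p = 0.0143, without mutant sample 1), hair follicle -0.32 and 0.0048, leukocyte -0.045 and 0.21, sex-linked -0.24 and 2.54, simple keratins -0.029 and 0.39, stress -0.093 and 0.11, suprabasal -0.26 and 0.14, and junction -0.0027 and 0.12. For genes they were Kdr -0.013 and 0.42, Krt1 -0.018 and 0.22, Krt14 -0.46 and 0.012, Krt5 -0.45 and 0.0045, Lor -0.23 and 0.078, Tfap2a -0.30 and 0.0031, Tfap2e -0.26 and 0.27, and Trp63 -0.11 and 0.073.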

Other observations

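The tests on mutant sample 1, on the chromosome of Tfap2c, on the keratinocyte share, on the Lce families and on splits for the number of lists, and the genes named without mutant sample 1, were chosen after the results were seen. Without mutant sample 1, 39 probe sets passed in limma, 3 of them unnamed and the others from 31 named genes. All 39 had the same sign with all 6 samples, which is nearly fixed, since the samples that chose them are among the 6. They included Slc2a3, a glucose transporter, with a log2 difference of 2.33, and Vnn1, a pantetheinase, with 2.54. Bmp2, a ligand of the hair placode and epidermis, differed by -1.27 and Il18, a cytokine made by keratinocytes, by -1.79. In mutant sample 1 itself Bmp2 was at 2225, against 719 and 704 in mutant samples 2 and 3.

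Sftpd rose in the mutant samples. RNA of lung would bring Sftpc, the most abundant surfactant transcript, but Sftpc differed by 0.331 on the log2 scale with overlapping samples (102 in mutant and 82.1 in control samples on average), which argues against lung RNA. Napsa, another lung marker, was high in mutant sample 1 alone (6368). A chromosome segment carried along with the mutated allele would not hold Sftpd, which lies on another chromosome than Tfap2c. An action of such a segment on Sftpd from a distance was not tested. Of the 98 tested neighbours of Tfap2c, 4.08% had an unadjusted p under 0.05, against 3.41% of other genes (Fisher's exact two-sided p = 0.579). That share does not bear on Sftpd itself. The mutation that the design names stays open, untested beyond the comparison of the groups.

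The number of changed probe sets, whichever genes they are, was 1 in the real split and at most 7 in the others; 4 of the 10 splits gave as many, and 10 splits are too few for a share under 0.05. The split with 7 set mutant sample 1 with control samples 1 and 2, the 3 samples with high Xist, against those with high Eif2s3y. Probe sets of X-linked and Y-linked genes were kept in the splits. This count can therefore include sex-linked genes, and it does not by itself show a structure beyond them. For the 771 probe sets with an unadjusted p under 0.05, 8 of 10 splits gave as many, with 1560 as the highest other value. The number of lists past the threshold was 3 in the real split and 1 to 12 in the others, 4 of which gave more than the real one (5 of 10 as many).

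Mutant sample 1 stood apart from the other 5 samples. A difference between Xist-expressing and other embryos is argued against as the main source. Control samples 1 and 2, also with high Xist, scored 9.94 and 0.352 on the first component, and control sample 3 scored 13. The corresponding differences in the mutant and control groups correlated at 0.0822 across probe sets, without X-linked and Y-linked genes. Each of those differences sets 1 array against 2, so the correlation cannot exclude a smaller part. RNA of uterus is a candidate source: 14 uterus markers outside the 40 most different of the tested and named probe sets had a median difference of 1.01 (bootstrap SE 0.223) between that sample and mutant samples 2 and 3, just over the bound of 1, and 11 of 14 were highest in it, with Cnn1 at 2800 against at most 61.1. Hox genes and smooth muscle genes among these markers are made in embryonic skin too. A smaller share of keratinocytes cannot be told apart, since the lowest of the fibroblast, muscle and endothelium medians was -0.313 (bootstrap SE 0.181), nor can degraded RNA, since the 3' to 5' ratio of beta-actin was highest in that sample (1.69 against 1.36 to 1.53) and that of Gapdh was not (0.804 against 0.757 to 0.82).

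The cornified envelope list was lower in the mutant samples by camera with the preset correlation, and did not pass with an estimated one (adjusted p = 0.65). The negative median does not rest on mutant sample 1 alone, since it was -0.423 (bootstrap SE 0.18) without that sample. The SE takes genes as independent, while their estimated correlation was 0.445 without that sample, so it cannot settle more. Repeated counting of near-identical paralogs stays open, since the median of the 29 genes outside the Lce1 and Sprr2 families was -0.159 (bootstrap SE 0.125). The bound written before the test, a median below 0 with a camera p under 0.05, was met (p = 0.00374 at the preset correlation; adjusted p = 0.846 with an estimated one), but it set no spread, and the median lies less than 2 SEs below 0, a condition added after the value was seen. A smaller share of keratinocytes in the mutant samples stays open too, since the suprabasal and basal medians lay above the cornified median by only 0.269 and 0.312 (bootstrap SEs 0.221 and 0.226). For mutant samples 2 and 3 by themselves, the gaps without mutant sample 1 were 0.564 and 0.416 (SEs 0.194 and 0.20). The smaller gap is 2.08 SEs, and the SEs take correlated genes as independent, so this does not decide it. Both gaps passed 2 SEs in 2 of 6 leave-outs (mutant sample 1, control sample 3), and the SEs cover genes, not samples. The real split had a median 0.377 from 0 and the highest of the others 0.414; 3 of 10 splits gave as much, too few splits for a share under 0.05. The 3 splits that set mutant samples 1 and 3 with 1 control sample against the rest had medians 0.356 to 0.414 from 0, and the gap between Lce3 and Lce1 genes was 2.75 in the real split (1 of 10) and at most 2.19 in the others.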
